A study of Arabidopsis thaliana with 12 samples.

How the data were processed

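Total RNA of 6 WT and 6 toc132 samples of Arabidopsis thaliana had been measured on an expression array, with 1 value per probe and sample. The values are linear intensity values as deposited by the authors, on an arbitrary scale from 0 to 100. The array type, scanner, background correction and scaling were not given in the sources used here, so the meaning of the exact zeros is unknown, and fold changes depend on any background removal before deposit. Groups and replicate numbers were taken from the sample titles, and 0 columns remained without a sample. The values were not a ratio to WT, since the WT columns held skewed intensities as the toc132 columns did, although the widths of the distributions differed between the groups. Summed intensities lay within 3536 to 3857 per sample. The 8 probes with the highest mean over all samples took between 7.43% and 14.2% of the sum of a sample.

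Values of 0 were treated as missing and the rest were put on the log2 scale. By a rule fixed before the data were examined, columns were to be kept as deposited if their log2 medians differed by under 0.1 and their interquartile ranges by under 10%, and otherwise quantile normalised. The medians differed by 0.72, so quantile normalisation was used. The interquartile ranges lay between 1.92 and 2.08 in WT and between 1.56 and 1.89 in toc132, without overlap. Quantile normalisation gives all samples the same distribution, so it removes this difference in width between the groups. The normalisation moved the median log2 difference over all probes from 0.03 to -0.06. A probe needed at least 4 values in each group, which left out 249 of the 3439 probes, among them 70 at 0 in all samples. Fits without a whole set needed fewer values, allowing a single missing value in the reduced group, so the number of probes tested could differ there.

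Of the 3439 probes, 692 were annotated with 1 gene, 870 with several and 1877 with none. No gene was named from a probe with several. For 690 of the 692, the gene was matched by its identifier to the RefSeq gene table of assembly TAIR10.1, which served only for names. No coordinates are given, since the files name no build.

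The 2 groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided), with Benjamini-Hochberg adjustment over the 3190 probes tested and a threshold of 0.05, and with no further covariate. A fold of at least 2 defined the largest differences. Differences are toc132 minus WT, with the SE of the moderated fit. Lists of genes were tested with camera at a preset correlation of 0.01 where at least 3 members were measured, with Benjamini-Hochberg adjustment over those lists. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

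The replicate numbers are shared by both groups in the titles, and no label says what they mark. Whether they pair the samples was checked by correlating, across the 2907 probes complete in all samples, the deviations of same-numbered WT and toc132 samples from their group means. The 6 correlations were 0.33, 0.30, 0.20, 0.15, 0.44 and 0.39, all above the limit of 0.1, and 11 of the 12 samples correlated best with their own number among the samples of the other group. By the rule that all 6 exceed that limit, the numbers were read as pairing the samples. The other number of the same set also correlated above the limit in all 6 cases (0.15 to 0.33), and for number 4 more than its own (0.160 against 0.153), so the check does not separate pairing by number from sets of close samples. The main fit had no block, as fixed before the data were examined. The result with the replicate number as a block is given where it moves a count.

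Genes were named by a rule fixed before the data were examined. It took TOC132, the called genes of largest difference, and the called members of each list or, with none called, the member with the smallest p. With fewer than 10 probes called it took the 10 with the smallest p. That last clause was read, after the fit had been seen, as limited to probes with a single gene above the lowest 25% in mean intensity. GLDH and AT1G03810 were added because they passed with the replicate block, and the other 2 members of the photosystem II list after their values were seen.

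Alternatives fixed before the data were examined were other scalings, filters on dim or incomplete probes, an offset before log2, the replicate block, other variance models, array weights, sets of close samples as a random block, each sample left out, and other tests of lists. The sets themselves were recognised from the data, so the random block rests on a grouping that was not fixed in advance. Averaging the sets, fitting them as a fixed block, leaving out whole sets, and adding probes with several genes of one list were chosen after seeing the data.

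The fits were tested on simulated data with 3190 genes, 200 of them changed, in groups of 6. With independent samples the comparison of 6 with 6 recovered 36% of genes changed 2-fold and 77% of those changed 4-fold, with 2 false calls. Samples were also simulated in sets of 2, each set with its own effect and with equal spread in both groups. No effect was shared by a number across groups, so the replicate block was not tested where it could help. The comparison of 6 with 6 made 186 false calls there and the replicate block 189. There were 7 with sets as a random block and 1 with sets averaged. The averaged fit then recovered 0% of genes changed 2-fold and 23% of those changed 4-fold, and the random block 22% and 66%.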

Results

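Gene expression was profiled by array in total RNA of Arabidopsis thaliana, ecotype Columbia 0, from the wild type (WT) and from the toc132 mutant. TOC132 is a receptor for preproteins at the outer envelope of the chloroplast, and the labels describe the mutant as impaired in protein import across that membrane. Each group held 6 samples, numbered 1 to 6 in both. The labels do not say that the samples came from separate plants, so p-values measure only the spread between these samples, which may be technical. Organ, age and growth conditions were not given in the sources used here. The table held 3439 probes with a deposited intensity between 0 and 100 in arbitrary units. The intensities of a sample summed to between 3536 and 3857, with a median per probe between 0.354 and 0.616, and between 174 and 277 probes of a sample were at 0. The number of arrays limits the precision. A total of 3190 probes had enough values above 0 to be tested, and 634 of them name a single gene. TOC132 itself was not analysed here, because no probe with a single gene carries its name, so the mutated gene could not serve as a check of the labels.

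The comparison of toc132 with WT addresses how transcript levels differ when this import receptor is impaired. Among probes with a single gene, the smallest p-values belonged to 4 genes with lower and 6 genes with higher intensity in toc132, and none of them passed the test after adjustment. CSLA01 (AT4G16590), of the cellulose synthase-like A family of glucomannan synthases, had a mean log2 intensity of -0.31 ± 0.39 (SD, n = 6) in WT and -1.35 ± 0.43 (SD, n = 6) in toc132, which is 0.489-fold of WT. GLR2.7 (AT2G29120), a glutamate receptor-like channel, stood at 0.489-fold of WT and AT2G37510 at 0.474-fold, and both were lower in toc132 for each of the 6 numbers. PRA1.B6 (AT5G07110), of the prenylated Rab acceptor family, stood at 2.16-fold of WT. AT5G35100 was at 2.08-fold and AT4G32060, which encodes a calcium-binding regulator of mitochondrial calcium uptake, at 1.88-fold of WT. For AT5G35100 the close samples WT 1 and WT 2 lay at -0.31 and -1.84 (log2), the highest and lowest WT values. With sets of close samples as a random block, its unadjusted limma p was 0.206.

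The larger of these differences belonged to 4 genes. AT5G55580, of the family of mTERF proteins that act on organelle transcripts, was at 3.26-fold of WT, with a log2 difference of 1.70 ± 0.47 (SE). The pentatricopeptide repeat gene AT5G39980 was at 2.91-fold (log2 difference 1.54 ± 0.42, SE) and AT5G46560 at 3.18-fold (1.67 ± 0.45, SE). SRX (AT1G31170), the sulfiredoxin that restores overoxidised peroxiredoxins, was at 0.381-fold of WT (log2 difference -1.39 ± 0.38, SE). These 4 differences were uneven over the sample numbers. For AT5G55580 the log2 difference was -0.02 between the samples numbered 1 and 2, 2.43 for 3 and 4, and 2.70 for 5 and 6. For SRX the same 3 values were 0.33, -2.09 and -2.41. For AT5G39980 they were 0.65, 1.94 and 2.03, and for AT5G46560 they were 0.12, 2.54 and 2.34. The limma adjusted p (Benjamini-Hochberg) was 0.119 for each of these 10 genes.

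**Figure D1:**
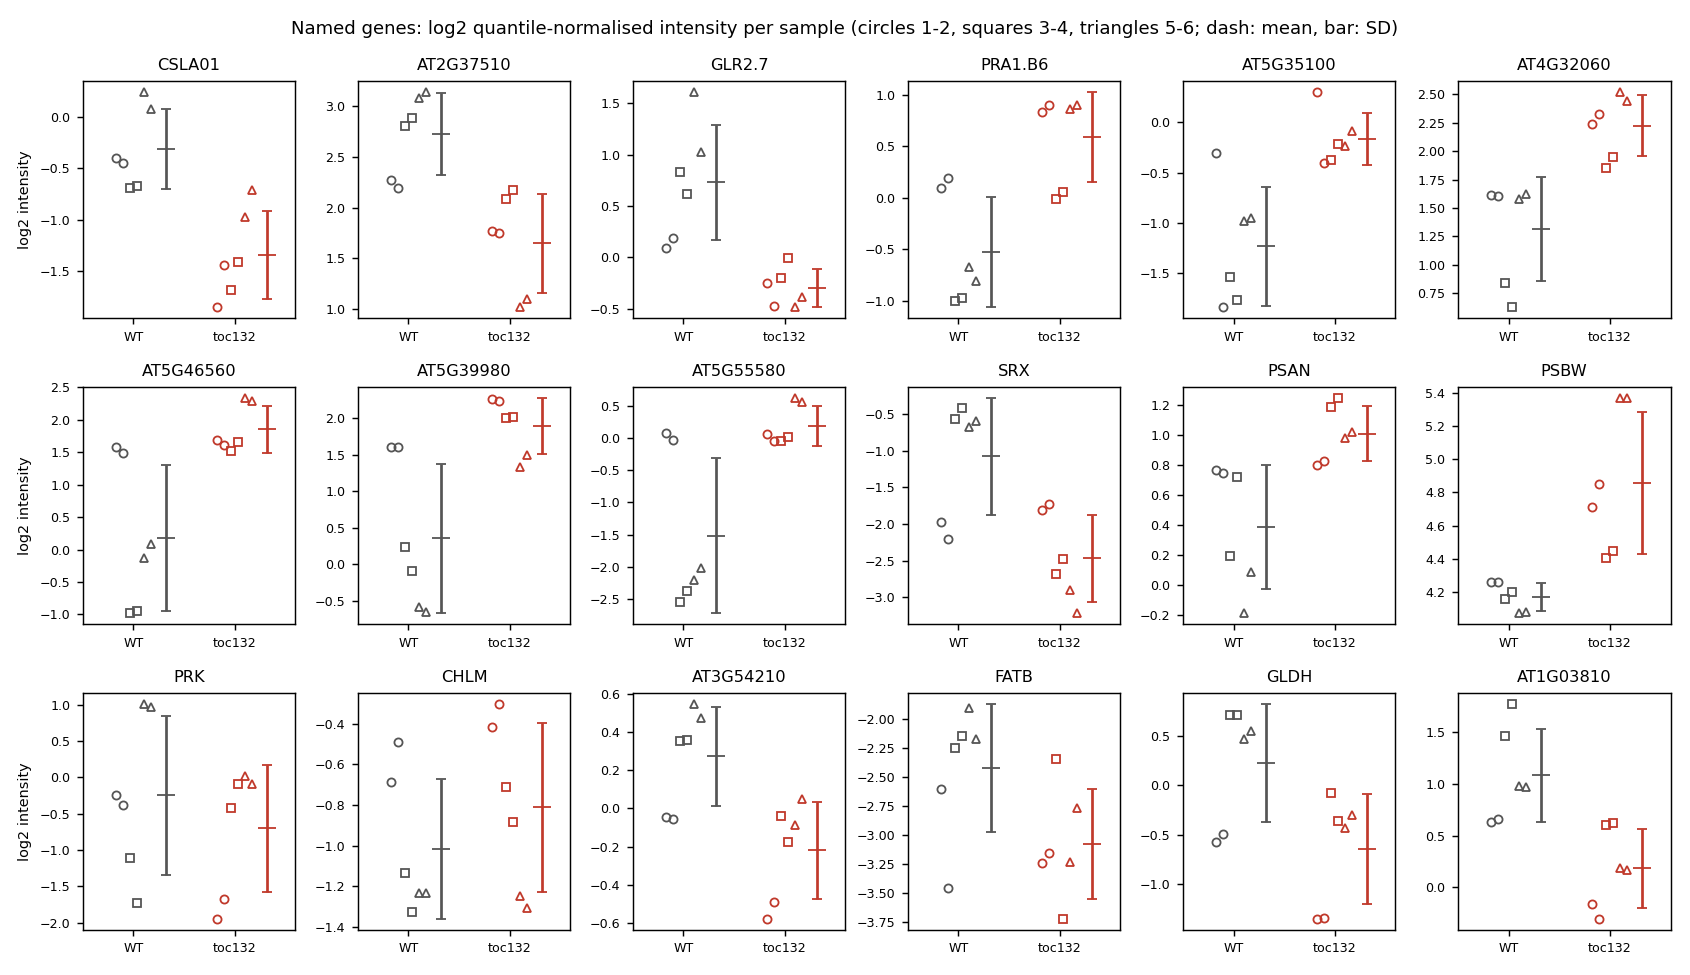
Log2 quantile-normalised intensity (vertical axis, arbitrary units) of the 18 named genes in each of the 6 WT and 6 toc132 samples, with circles for numbers 1 and 2, squares for 3 and 4, triangles for 5 and 6, a dash for the mean and a bar for the SD. For AT5G55580, WT samples 1 and 2 lie at the level of the toc132 samples, whereas for CSLA01 the toc132 mean of -1.35 lies below the WT mean of -0.31 and each toc132 sample lies below the WT sample of its number.

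With limma and Benjamini-Hochberg adjustment, 0 of 3190 probes passed an adjusted p of 0.05. At an unadjusted p under 0.05 there were 807 probes, where 160 are expected by chance, and a test with unequal variances per probe gave 0 probes after adjustment and 657 before it. These counts treat the 6 samples of a group as independent: limma gave 257 probes at an unadjusted p under 0.05 with the close samples of a set as a random block, and 147 with them averaged. The smallest adjusted p in limma was 0.0722, for probe 3533, which has no named gene and stood at 0.332-fold of WT (log2 difference -1.59 ± 0.25, SE), lower in toc132 in each of the 3 sets of numbers. With the replicate number as a block, 21 probes passed in limma, 5 higher and 16 lower in toc132, each with an adjusted p of 0.0464. Of these 21 probes, 15 have no named gene, 3 name several genes, and 3 name a single gene: CSLA01, GLDH and AT1G03810. GLDH (AT3G47930), the enzyme of the last step of ascorbate synthesis, was at 0.546-fold of WT (log2 difference -0.87 ± 0.14, SE with the block). AT1G03810 was at 0.537-fold of WT (-0.90 ± 0.14, SE with the block), and both genes were named after their values were seen. The count depended on the treatment of the samples: averaging the samples numbered 1 and 2, 3 and 4, and 5 and 6 of each group gave 0 probes, with or without pairing by number. Without WT sample 1 it was 387 probes, and without WT sample 2 it was 422.

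Genes of photosynthesis and plastid metabolism were sparsely covered by probes that name a single gene. Probes with several genes or no annotated gene were left out here and may cover more of them. Of 328 genes in 17 lists fixed before the data were examined, 13 had a tested probe of their own, in 6 lists. Of these 13 members, 8 were higher and 5 lower in toc132, and 0 passed the test over all probes. Without WT samples 1 and 2, 5 of the 13 passed, near the share of all probes (1131 of 3439, tested or not). The 3 measured members of photosystem II and its antenna were all higher in toc132 under each of the 4 scalings tried, with a median log2 difference of 0.69. PSBW (AT2G30570), a small subunit of photosystem II, was at 1.61-fold of WT (log2 difference 0.69 ± 0.22, SE) and higher for each of the 6 numbers. LHB1B2 (AT2G34420), a chlorophyll-binding antenna protein, was at 1.99-fold (0.99 ± 0.42, SE), with log2 differences of -0.07, 1.26 and 1.78 for the numbers 1 and 2, 3 and 4, and 5 and 6. Its value is uncertain, because the gene belongs to a family of near-identical copies. PSBY (AT1G67740), another small subunit, had a log2 difference of 0.26 ± 0.36 (SE). It was 0.14 with median centring and turned to -0.24 without WT samples 5 and 6. For the same 3 sets of numbers it was -0.30, 0.29 and 0.78, so PSBY, like LHB1B2, was not higher for numbers 1 and 2. Tested against all other probes with limma's camera, the list had p = 0.0418 and an adjusted p of 0.0836 over the 2 lists tested, and an adjusted p of 0.146 with an estimated correlation. Adjusted over the list alone, 1 of the 3 members passed, PSBW, which no longer did with sets as a random block (limma adjusted p = 0.0805) or in the values as deposited (0.0858).

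The nuclear-encoded plastid ribosomal proteins had 4 measured members, 1 higher and 3 lower in toc132, and limma's camera gave an adjusted p of 0.456. In the values as deposited, 1 of the lower members was slightly higher than WT (log2 difference 0.03). AT3G54210, plastid ribosomal protein RPL17, had the smallest p of the list, at 0.711-fold of WT (log2 difference -0.49 ± 0.20, SE, limma adjusted p = 0.156), and 0 of the 4 passed adjusted over the list alone. The other lists had 1 or 2 members each and could not be tested as lists. PSAN (AT5G64040), a subunit of photosystem I, was at 1.54-fold of WT with a limma adjusted p of 0.132. Its log2 differences were 0.05, 0.76 and 1.05 for the numbers 1 and 2, 3 and 4, and 5 and 6. FATB (AT1G08510), a plastid acyl-ACP thioesterase, was at 0.635-fold with a limma adjusted p of 0.193. Its probe was dim, with a mean log2 intensity of -2.43 in WT and -3.08 in toc132. The close samples toc132 3 and 4 differed there (-2.35 and -3.73). The log2 difference of FATB, -0.65, was -0.36 in the values as deposited. Adjusted over the list alone each of these passed, but with 1 member that adjusts for nothing, and neither did in limma with sets as a random block (adjusted p over the list alone of 0.118 for PSAN and 0.430 for FATB), nor FATB in the values as deposited (0.328). In the Calvin cycle list PRK (AT1G32060), phosphoribulokinase, was at 0.730-fold of WT and the other member was higher. In chlorophyll synthesis CHLM (AT4G25080), the methyltransferase of magnesium protoporphyrin, was at 1.15-fold of WT, and the other member was higher by 0.05 (log2) and lower than WT under the other 3 scalings. The limma adjusted p was 0.584 for PRK and 0.594 for CHLM, each of which turned direction when a set of samples was left out, and 0 members of these 2 lists passed adjusted over the list alone. The other 11 lists had 0 members measured by a probe with a single gene: import machinery, electron transport and ATP synthase, plastid chaperones and proteases, isoprenoids, starch, photorespiration, sulfate and tryptophan, antioxidants, defence and senescence, markers of root and seed, and reference genes.

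The samples of each group fell into 3 sets of consecutive numbers, recognised from the data and not from the labels. Across probes, which are not independent replicates, Pearson's r of log2 intensities was 0.901 to 0.975 within a set. Between sets it was 0.806 to 0.894 among toc132 samples and 0.533 to 0.723 among WT samples. WT samples 1 and 2 had a median r of 0.707 with WT 3 and 4 and 0.539 with WT 5 and 6. With the 3 toc132 sets their median r was 0.909, 0.922 and 0.825. The first principal component held 49.1% of the variance and separated WT samples 3 to 6 from the other 8 samples. On the second, with 20.8%, WT samples 3 and 4 stood at 32.3 and 32.9. WT samples 5 and 6 stood there at -15.0 and -15.9, on the side of toc132 5 and 6 (-26.2 and -26.6). The remaining samples lay between 0.52 and 4.70.

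**Figure D2:**
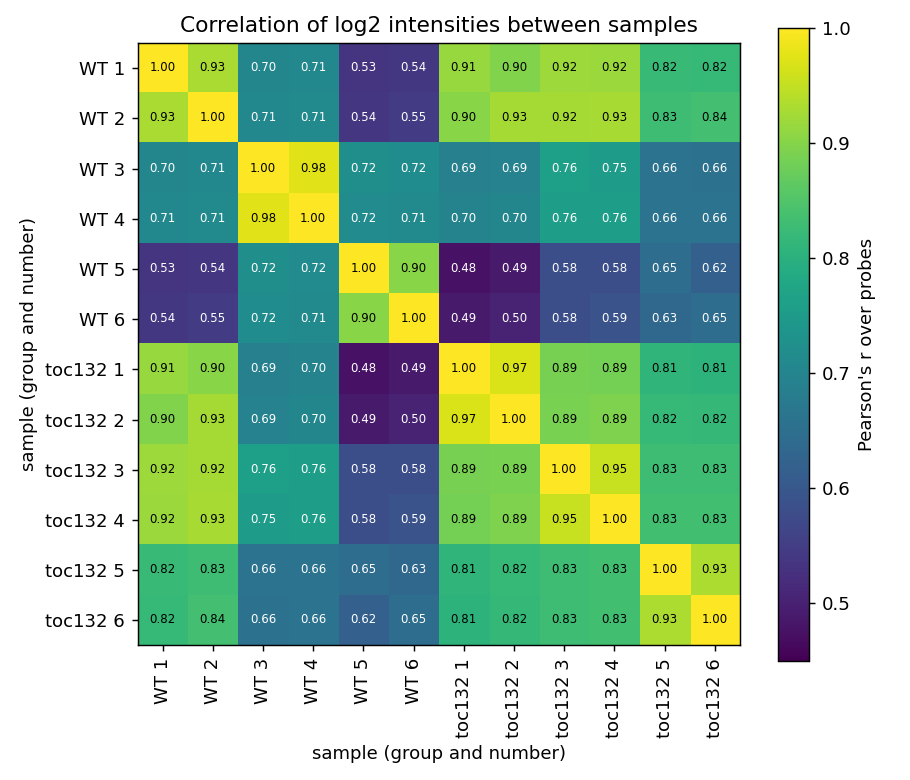
Pearson's r across probes between the log2 quantile-normalised intensities of each pair of samples, with the 6 WT samples followed by the 6 toc132 samples on both axes and the colour scale giving r. WT samples 1 and 2 have median values of 0.909, 0.922 and 0.825 with the 3 toc132 sets, above their medians of 0.707 and 0.539 with the other WT samples.

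The difference between toc132 and WT was taken within each set of numbers, over 3104 probes. Its SD over probes was 0.63 (log2) for numbers 1 and 2, 1.14 for 3 and 4, and 1.36 for 5 and 6. The differences of numbers 3 and 4 correlated with those of 5 and 6 at r = 0.54 across probes, and these sets share no sample. Those of numbers 1 and 2 correlated with them at r = -0.14 and 0.07. The direction was the same in all 3 sets for 37.4% of probes (582 higher, 578 lower), where 35.0% is expected if the directions of numbers 1 and 2 are unrelated to the 70.9% of probes with the same direction in the other 2 sets.

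**Figure D3:**
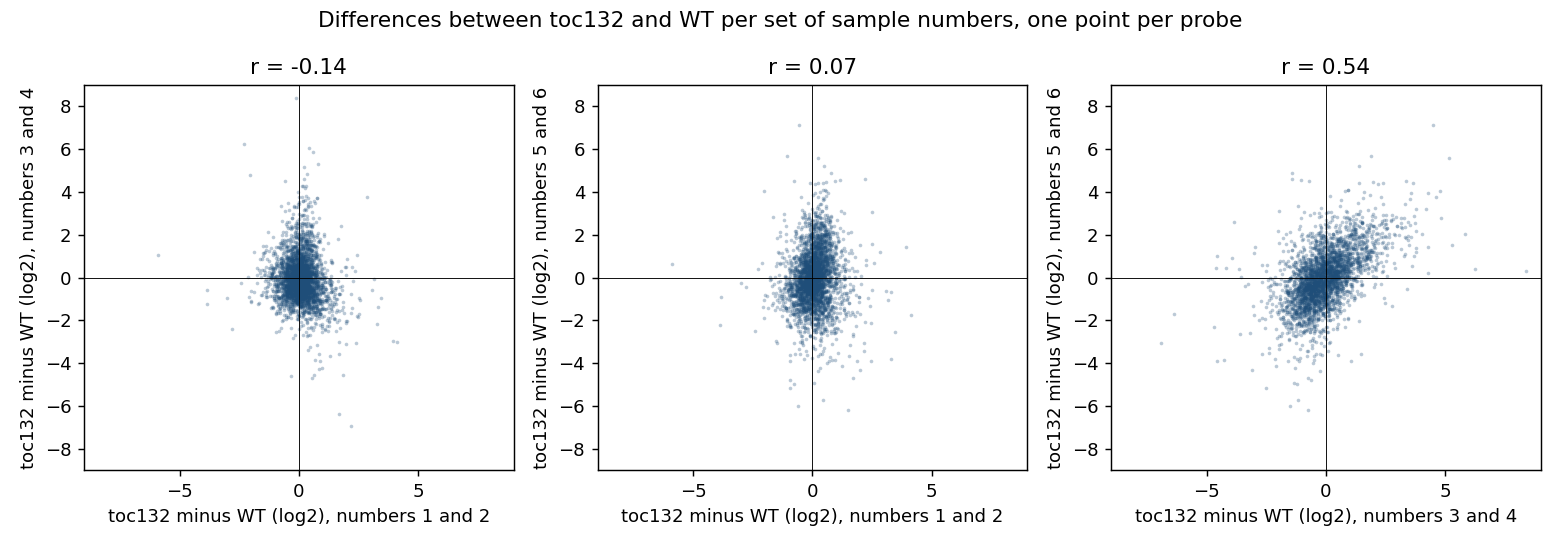
Log2 difference between toc132 and WT for each probe (1 point per probe) in 1 set of sample numbers against another set, with both axes in log2 units. The points follow a common direction for numbers 3 and 4 against 5 and 6 (r = 0.54) and not for numbers 1 and 2 against 3 and 4 (r = -0.14) or 5 and 6 (r = 0.07).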

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

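The averaged or left-out sets, the fixed block of sets and the added list probes were chosen after seeing the data. The count of 0 probes stayed 0 under 4 planned settings: values as deposited, median centring, cyclic loess, and probes above 0 in all samples. It stayed 0 with unequal variances, with sets as a random block (257 at an unadjusted p under 0.05 in limma) and with sets averaged (147) or averaged and paired (346). Quantile normalisation, also listed as an alternative, is the setting reported. Without the dimmest 25% of probes, with an offset before log2, and with a trended robust eBayes, 1 probe passed in each, the lower probe 3533 with a fold above 2, at limma adjusted p of 0.0365, 0.041 and 0.048 against 0.0722; the cause was not tested.

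With the replicate number as a block, 21 probes passed, 5 higher, 16 lower and 16 at least 2-fold. The block changed no call of a list. With sets of 2 as a fixed block it was 892 (482 higher, 410 lower, 384 at least 2-fold); this fit and the replicate block count the close samples of a set as independent. Array weights gave 1162 (586 higher, 576 lower, 646 at least 2-fold). The weights were 0.40 for WT 1 and 2, 2.18 and 2.23 for WT 3 and 4, and 0.38 and 0.39 for WT 5 and 6. The toc132 samples had weights of 0.87 to 2.36. The close samples WT 3 and 4 thus carried most of the WT weight, and this fit too counts them as independent.

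Leaving out each sample gave 0 to 422 probes, 0 to 274 higher, 0 to 148 lower, 0 to 339 at least 2-fold, and 0 lists. It was 387 without WT 1, 422 without WT 2 and 0 without any of the other 10. Without WT 1 and 2 together it was 1131 (564 higher, 567 lower, 808 at least 2-fold), and without the numbers 1 and 2 of both groups 829 (440 higher, 389 lower, 643 at least 2-fold). Leaving out any other set, in 1 group or both, gave 0. WT 1 and 2 resemble the toc132 samples, so leaving them out raises a count by construction.

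The number of lists passing went from 0 to 1 in camera with sets as a random block (photosystem II, adjusted p = 0.0385). It also did with fry (adjusted p = 0.0264), which tests the members without comparing them with other genes. In camera with an estimated correlation the number stayed 0 (photosystem II, adjusted p = 0.146). With probes of several genes of one list added, camera gave photosystem II an unadjusted p of 0.151 and an adjusted p of 0.454 over the 3 lists that then had enough members. Of 944 values of the 27 probes named by gene or number, 939 kept their direction, 129 of them passing the threshold. Most of these probes were picked for their difference in the same samples, so a kept direction was likely beforehand and says little about robustness. PRK turned to 0.16 without WT 5 and 6, 0.098 without toc132 1 and 2, and 0.066 without numbers 1 and 2 of both groups. PSBY turned to -0.24 without WT 5 and 6. CHLM turned to -0.020 without toc132 1 and 2; the causes were not tested. No alternative could be run for TOC132, which was not analysed here. Signal over background was not given in the sources used here, so what it limits was not assessed.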

Other observations

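The splits of the samples were planned, but the sets that some of them keep whole were recognised from the data. The tests on the position of WT samples 1 and 2 and on the closeness of consecutive numbers were chosen after the result was seen. So were the genes of the next paragraph.

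Differences of at least 1 (log2) in the same direction in the samples numbered 3 and 4 and in those numbered 5 and 6 were seen for 502 probes, 275 higher and 227 lower in toc132, and 12 of the 502 had such a difference in numbers 1 and 2 as well. With limma fitted without WT samples 1 and 2, 1131 of the 3439 probes, tested or not, passed. Leaving out these samples, which resemble toc132, raises a count by construction, and the fit counts the close samples of a set as independent. Among the passing probes with a single gene above the lowest 25% in mean intensity, 3 had the largest higher values in toc132. They were AT5G46390, AT4G35660 and AT2G30100. For AT2G30100 the log2 difference was 3.32 for numbers 3 and 4, 3.44 for 5 and 6 and 0.38 for 1 and 2, and for AT4G35660 it was 4.80, 4.05 and -2.04 in the same order. For AT5G46390 it was 5.85, 2.04 and 0.60. The 3 with the largest lower values were AT2G36480 (-1.57, -2.85 and -0.27), AT4G31210 (-1.74, -1.97 and 0.19) and AT4G20300 (-1.26, -2.36 and -0.31). Of the 13 measured members of the fixed lists, 5 passed in that limma fit, a share near that of all probes. The higher ones were LHB1B2 (log2 difference 1.58, adjusted p = 0.00105), PSAN (0.79, 0.0136) and PSBW (0.72, 0.0377). The lower ones were FATB (-0.97, 0.0151), from a dim probe, and the plastid ribosomal gene AT3G54210 (-0.65, 0.0204). Neither list tested passed there with camera, with adjusted p of 0.0933 for photosystem II and 0.422 for the plastid ribosomal proteins. Of 1102 of the 1131 probes with a difference in numbers 1 and 2, 682 (61.9%) had the same direction there, with a median of 0.13 against 1.29; toc132 samples 1 and 2 enter both values, so they are not independent.

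WT samples 1 and 2 lay among the toc132 samples, and a swap of labels between the groups would need a toc132 set out of place; the closest, toc132 3 and 4, had a median r of 0.758 with WT 3 and 4, above the 0.717 between WT 3 and 4 and WT 5 and 6, but of 0.888 and 0.831 with the other toc132 sets, so a swap would still leave a WT set among the toc132 samples. Scaling or dim probes as the whole cause are argued against by the ranks of deposited values in the 860 brightest probes, where WT 1 and 2 stood 0.505 closer to toc132 (0.851) than to WT 3 to 6 (0.345). A batch shared by the same numbers is argued against as the whole cause. Between numbers 1 and 2 and the other sets, the differences correlated at most at 0.0731 (Pearson) and 0.140 (Spearman). Between numbers 3 and 4 and 5 and 6 they correlated at 0.539 and 0.545. A shared batch cancels in differences within a number, so it would leave a genotype effect in every set. If the mutation altered little, low correlations would arise with such a batch too, but the 0.539 would then need another cause. The median r of WT 1 and 2 was 0.922 with toc132 3 and 4 and 0.909 with toc132 1 and 2. Those values decide nothing here, since their ranges overlapped (0.918 to 0.929 and 0.897 to 0.925). Such a batch stays open as part of the cause, since deviations of same-numbered samples correlated at 0.33 and 0.30 for numbers 1 and 2. A wrong label on WT 1 and 2 remains a candidate explanation, as their lowest median r with a toc132 set, 0.825, was no lower than that between toc132 sets, but the same value would arise if the mutation altered little and WT 3 to 6 stood apart for another reason. A batch of WT 3 to 6 and an effect of the genotype cannot be told apart, since either may give the correlation of 0.539 between the differences of numbers 3 and 4 and of 5 and 6, and the level of TOC132 was not analysed here.

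For the comparison of 6 with 6 samples, the splits decide nothing about the count passing the adjusted threshold, since each of the 100 drawn (100 of 100) must reach the real count of 0; the highest other was 21. For the count at an unadjusted p under 0.05, 3 of 100 gave as many as the real 807 (highest other 969), which excludes chance only if samples are independent. With the 6 sets kept whole, 10 splits are too few for a share under 0.05; the real one gave 807 and 2 others as many (3 in all), and the highest, 1318 with 788 passing after adjustment, set WT 1 and 2 with toc132 1 to 4 against the rest, which points to a structure of the samples. With the replicate block, 2 of 32 ways of exchanging the groups within pairs gave at least the real 21, so chance cannot be excluded for the 21. The other gave 59 when the groups were exchanged in the numbers 3 to 6. Apart from the sign, that equals exchanging only the numbers 1 and 2. It does not decide the labels of those numbers, since before adjustment the real assignment gave more probes (1086 against 1039). At an unadjusted p under 0.05 only the real assignment (1 of 32) reached 1086, with 1039 as the highest other. Of the 32, 28 part the close samples of a set, which may lower a count and was not tested. Their counts of 5 to 895 overlapped those of the 4 that keep sets whole (102 to 1086). These 4, 1039 among them, are too few for a share under 0.05.

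Samples of one group with consecutive numbers were close, with a consensus correlation of 0.872 within sets. That is consistent with one RNA or hybridisation measured in duplicate, as a hypothesis, though plants grown or processed together may give it too, and no biological explanation was tested. If the sets are repeats, each group holds 3 independent samples, and the fits of 6 with 6 count too many.

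Of the probes left untested, 3 (539, 2007 and 2890) were above 0 in 4 or 5 WT samples and in 1 toc132 sample.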
